A study of Homo sapiens with 8 samples.

How the data were processed

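RNA was measured in human brain organoids grown from H1 embryonic stem cells with a cerebral organoid kit. After 130 days of culture, one set stayed in normal medium and another received medium with 10% human serum for 12 days. Per the labels, cells were lysed without crosslinking, and RNA was extracted either from the whole lysate (input) or after immunoprecipitation of PHGDH (RNA immunoprecipitation, RIP). PHGDH is the enzyme that starts serine synthesis from a glycolytic intermediate. Each library was made from 10 ng of RNA with a low-input kit that does not keep the RNA strand. There were 8 libraries in 4 groups of 2: input and RIP, each without and with serum. No libraries from a control antibody were analysed here, so input RNA was the only background.

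The deposited table holds counts, namely whole read counts per gene that were neither scaled nor pooled by the authors. The submitters' processing notes name fastp 0.23.2, STAR 2.5.4b, SAMtools, featureCounts 2.0.1 and the genome build GRCh38, without their settings. Genes are identified by RefSeq symbol. The table had 44811 lines, of which 96 carried no gene name and 19 gene names stood on lines broken across several lines. These were left out, which kept 44696 genes. Counts without a gene name made up 0.160 to 0.418% of a library. Gene classes and chromosomes came from a table of reference genes, which matched 42297 of the genes (41911 by symbol and 386 by an older symbol). Of the 11068 genes tested, 10997 were matched.

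Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and summarised in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. In edgeR, genes were filtered with filterByExpr (minimum count of 10) and libraries were scaled by TMM. All 8 were fitted in one model with 4 group means and 4 residual degrees of freedom. That model takes one spread per gene from inputs and RIP libraries together, which can understate the spread of RIP libraries in RIP against input. The quasi-likelihood F-test (two-sided) gave p-values, adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. CPM in the text means TMM-normalised counts, as CPM, over the tested genes, unless a total or a share is named. Fold changes are given as log2 values with the standard error (SE), and levels as mean ± SD of 2 libraries per group. The 4 comparisons were RIP against input without serum, RIP against input with serum, the difference between these enrichments (the interaction), and serum against no serum in the input libraries. The same edgeR test on the 4 input libraries alone is given beside the last. That test was among the alternatives chosen beforehand, but naming genes and testing gene lists in it was decided after the data had been seen.

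Gene lists (32, covering pathways, RNA classes and cell type markers) were tested with camera (two-sided, preset correlation of 0.01) where at least 5 members were measured, which held for 25 lists, with adjustment over the lists of a comparison. Each test was repeated with the correlation estimated from the data. Members past the threshold were counted both over all genes tested and adjusted over the list alone. The microglia and endothelium lists had 0 measured members.

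Genes were named by a fixed rule. Among genes past the threshold with a mean of at least 5 CPM and both replicates of one group above both of the other, the 10 with the largest and the 10 with the smallest log2 fold change qualified, except clone or locus identifiers. Where fewer than 5 qualified, the 5 smallest p-values were taken as well. Up to 4 members of each list, by p-value, and a fixed set that included PHGDH, APP, BACE1, CHUK and HMGB1 in every comparison were added. The text names part of the genes that qualified. The comparisons, main tests, thresholds, lists and naming rule, and all alternatives except those described as added, were chosen before the data were examined.

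A count of 0 allows up to 3 counts in a library, equal to 1.76 to 2.93 CPM of a library's total and 1.58 to 3.31 CPM after TMM. A fold change against a group with 0 counts is given as a lower bound from 3 counts per library. Where a group held 1 to 3 counts, the ratio is given with its 95% counting interval. Reads had no molecular identifiers, so intervals and floors cover counting error only. An RNA can be at 0 in one RIP replicate and well above the floor in the other, so bounds and intervals do not limit the true fold change. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between samples that may be technical replicates. Because edgeR shares information on spread across genes, a p-value need not reflect how a gene's own replicates differed. On input libraries alone, the common coefficient of variation was 4.43%. Replicate numbers were not treated as pairs.

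Alternatives were DESeq2, RLE size factors, library size only, limma-voom with cyclic loess scaling, no filter, a minimum of 50 counts, a replicate block, only the 4 libraries of a comparison, and leaving out each library in turn. Added after the data were seen were limma-voom with separate input and RIP variances and all alternatives of the test on input libraries alone. The tests were also tested on simulated data in which 25 genes per fold change were altered among 11068. In the simulated RIP comparisons, genes unchanged by design had an unadjusted p under 0.05 in 8.59% (without serum) and 8.56% (with serum) of cases. There, the 8-library model recovered 0% of 4-fold changes, and 20% (without serum) and 32% (with serum) of 128-fold changes. A gene not past the threshold for RIP against input is therefore not shown to be unchanged. In the simulated serum comparison, the 8-library model recovered 0% of 2-fold changes, and the test on input libraries alone recovered 72%, with 9.18% of its calls false. DESeq2 calls were false in 63.3% (without serum) and 67.7% (with serum) of cases for RIP against input. Those of limma-voom with separate variances were false in 32.1 and 35.8%, and in 13.5% for serum in input. These shares belong to simulations with 200 genes altered. The real RIP comparisons called more genes, so the shares do not carry over to them.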

Results

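RNA recovered with PHGDH and total input RNA were sequenced from H1-derived brain organoids kept without serum or given 10% human serum, with 2 libraries in each of 4 groups. Total counts of input libraries were 1702736 and 1239435 without serum and 1618146 and 1693691 with serum. RIP libraries held 1076935 and 1372343 counts without serum and 1024836 and 1309229 with serum. Inputs detected 16588 to 17314 genes and RIP libraries 11350 to 11896. The 10 most abundant genes took 5.78 to 6.26% of input counts and 9.20 to 13.5% of RIP counts. Alignment was to GRCh38, and 11068 genes were tested.

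Replicate RIP libraries differed far more than replicate inputs. Across genes within a pair, the correlation of log2 CPM was 0.979 and 0.984 for the inputs and 0.607 and 0.668 for RIP (without and with serum), where genes are not independent replicates. The SD of log2 differences was 0.383 and 0.335 in inputs and 2.40 and 2.08 in RIP. Among genes with at least 50 counts in one RIP replicate, 413 of 5302 without serum and 242 of 5306 with serum had 0 counts in the other. In inputs this held for 0 of 6072 and 0 of 6209 genes. The coefficient of variation from edgeR was 4.43% between inputs and 107% between RIP libraries.

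**Figure D1:**
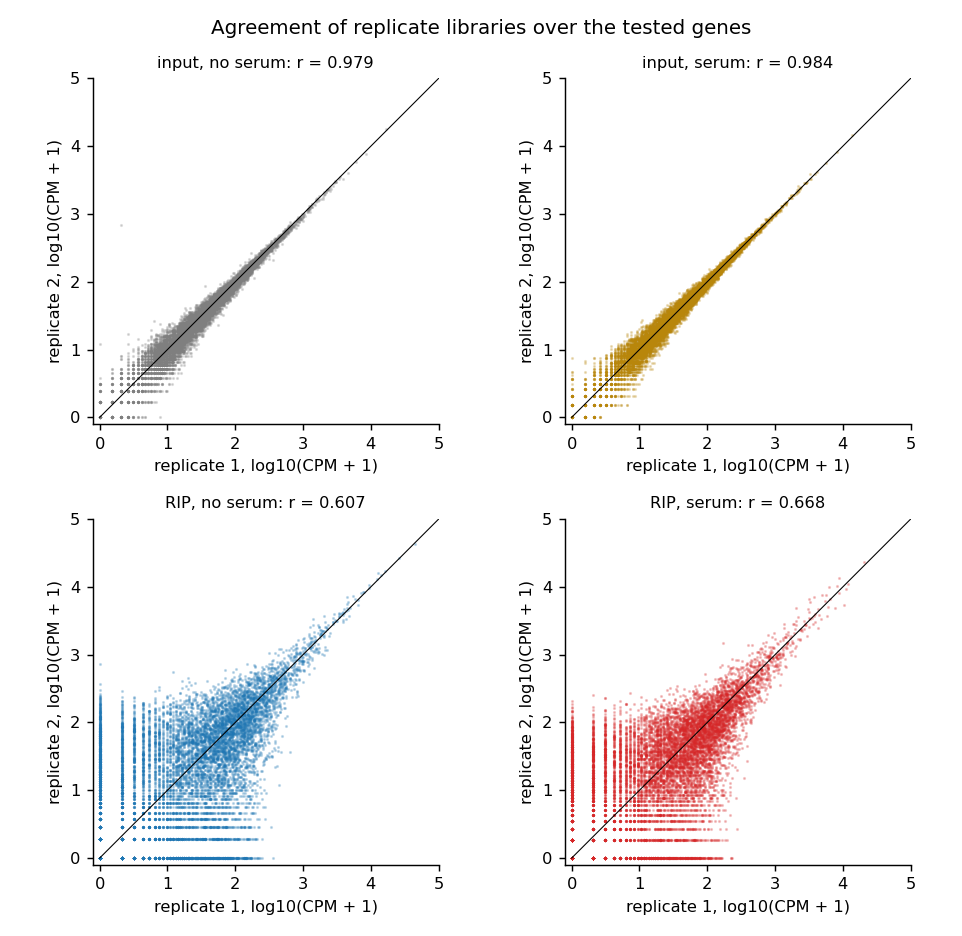
Each point is a gene, plotted as log10 (CPM + 1) in replicate 1 (horizontal) against replicate 2 (vertical), with one panel per group of 2 libraries. Input replicates follow the diagonal, while many genes in RIP lie on an axis, present in one replicate and at 0 in the other.

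The first comparison asked which transcripts were recovered with PHGDH relative to total RNA in organoids without serum. Most ribosomal protein transcripts (39 of 44) were higher in RIP, and part of the transcripts of mitochondrially encoded genes (9 of 13), nuclear oxidative phosphorylation (12 of 32) and general neuronal genes (6 of 16), while 5 of 19 of cholesterol synthesis were lower. Of these lists, only ribosomal proteins passed camera with the correlation estimated (the others had adjusted p of 0.190 to 0.334 with an estimated correlation). RPL35, a protein of the large ribosomal subunit, stood at 4622 ± 74.7 CPM in RIP against 112 ± 5.13 in input (log2 fold change 5.36, SE 0.15, edgeR adjusted p = 2.18e-05). ND4, a mitochondrially encoded subunit of respiratory complex I, stood at 26411 ± 819 against 3530.4 ± 7.43 CPM (2.90, SE 0.20, edgeR adjusted p = 0.000449). In edgeR, 1104 genes were higher in RIP and 1529 lower, and 4307 had an unadjusted p under 0.05, where 553 would be expected for exact p-values and more by chance here, since 8.59% of unchanged genes in simulated data were under 0.05. Of these, 619 of the lower genes had 0 counts in both RIP libraries and 21 of the higher had 0 counts in both inputs.

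Among the largest increases without serum were DCLK2, a kinase related to the microtubule-binding protein doublecortin, and PRR36, a proline-rich protein. DCLK2 rose from 4.91 ± 4.95 to 1266 ± 9.19 CPM (log2 fold change 7.92, SE 0.72, edgeR adjusted p = 0.0015) and PRR36 from 7.29 ± 0.642 to 1628 ± 663 CPM (7.79, SE 0.43, adjusted p = 0.000187). MMP25, a membrane-bound metalloprotease with 0 counts in both inputs, was at least 16.1-fold higher (edgeR adjusted p = 0.0216), and LINC02821 at least 17.9-fold higher (adjusted p = 0.0344). The calls of MMP25 and LINC02821 each ended in 4 of 12 alternatives and left-out libraries. MYPOP and SAP30, each with 1 count in the inputs, were higher at ratios of 321 (95% counting interval 56.9 to 12727) and 329 (58.4 to 13055), with edgeR adjusted p of 0.0123 and 0.0246. The pseudogenes FTH1P20, YBX1P2 and ARL2BPP9 and the antisense gene KLC2-AS1 also ranked among the largest increases, but they are uncertain because reads can be shared with parent or overlapping genes. Among the largest decreases were genes with 0 counts in both RIP libraries. Their bounds cover counting error only. Of 5302 genes with at least 50 counts in one of these RIP replicates, 413 had 0 in the other. CORO1C, an actin-binding coronin, was at least 105-fold lower (edgeR adjusted p = 0.000647), and SAR1B, a GTPase of vesicles leaving the endoplasmic reticulum, at least 83.9-fold lower (adjusted p = 0.000711). ELMO2, an engulfment and motility protein, was at least 80.0-fold lower (edgeR adjusted p = 0.00275), and CAP1, an actin regulator, at least 59.5-fold (0.00430). ADGRG1, an adhesion receptor, was at least 51.9-fold lower (edgeR adjusted p = 0.00448) and UBAP1, a sorting protein, at least 42.8-fold (0.00632).

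Of 44 measured cytosolic ribosomal protein transcripts, 39 rose and 1 fell (RPL15) without serum (43 and 1 adjusted over the list alone), with a median log2 fold change of 2.81. The camera adjusted p was 4.06e-34, and the call held with an estimated correlation (adjusted p = 0.00919). The listed transcripts made up 9.37% ± 0.585 of RIP counts and 1.65% ± 0.0118 of input counts. RPL19 rose by 3.98 on the log2 scale (SE 0.13, edgeR adjusted p = 3.06e-05) and RPS15 by 4.07 (SE 0.17, adjusted p = 7.07e-05). Single ribosomal protein genes are uncertain because they share reads with pseudogenes. Without input replicate 1 or without input replicate 2, 26 of the 44 rose in edgeR. Of 13 mitochondrially encoded genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 4.80e-06), a call lost when the correlation was estimated (adjusted p = 0.264 with an estimated correlation). Only 3 of the 13 rose without either one of the inputs, and under cyclic loess scaling 6 rose and 4 fell. ND1, also of complex I, rose by 3.06 on the log2 scale (SE 0.38, edgeR adjusted p = 0.00457). The mitochondrial genome took 5.19% ± 0.162 of RIP and 2.12% ± 0.0182 of input counts.

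Among 32 nuclear genes of oxidative phosphorylation, 12 rose and 1 fell without serum (13 and 2 adjusted over the list alone), with a camera adjusted p of 0.000123 (adjusted p = 0.190 with an estimated correlation). ATP5ME, a small subunit of ATP synthase, rose from 20.1 ± 0.562 to 1416 ± 305 CPM (log2 fold change 6.13, SE 0.31, edgeR adjusted p = 0.000149). UQCRQ of complex III rose by 3.21 (SE 0.22, edgeR adjusted p = 0.000447) and NDUFB2 of complex I by 3.71 (SE 0.30, adjusted p = 0.000818). Of 6 replication-dependent histone genes, H4C3 and H1-2 rose, by 3.95 (SE 0.37, edgeR adjusted p = 0.00168) and 4.72 (SE 0.64, adjusted p = 0.00602) on the log2 scale. Their counts were 2 higher and 0 lower, also adjusted over the list alone, and the camera adjusted p of 0.0468 was lost (adjusted p = 0.266 with an estimated correlation).

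Of 16 general neuronal and synaptic genes, 6 rose and 0 fell without serum (7 and 2 adjusted over the list alone; camera adjusted p = 0.0131; adjusted p = 0.334 with an estimated correlation). Under cyclic loess scaling 4 of these rose and 3 fell. GAP43, a protein of growing axons, rose from 886 ± 78.6 to 7948 ± 457 CPM (log2 fold change 3.17, SE 0.17, edgeR adjusted p = 0.000165). SYN1, which coats synaptic vesicles, rose by 6.07 (SE 0.78, edgeR adjusted p = 0.00486). Of 12 excitatory neuron genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.0421; adjusted p = 0.264 with an estimated correlation). Among these was SLC17A7, a vesicular glutamate transporter (log2 fold change 3.40, SE 0.44, edgeR adjusted p = 0.00506). NRGN, a postsynaptic calmodulin-binding protein, rose by 6.17 (SE 0.71, edgeR adjusted p = 0.00333). Of 19 cholesterol synthesis genes, 0 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.0468; adjusted p = 0.264 with an estimated correlation). HMGCS1 fell from 989 ± 90.6 to 199 ± 91.6 CPM (log2 fold change -2.31, SE 0.36, edgeR adjusted p = 0.00908). IDI1 fell by 2.37 on the log2 scale (SE 0.29, edgeR adjusted p = 0.00430) and MSMO1 by 3.17 (SE 0.50, adjusted p = 0.00969). Without either one of the inputs, 0 of these 19 fell.

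Of 17 amyloid precursor processing genes, 1 rose and 5 fell without serum (1 and 5 adjusted over the list alone), and the list was not past camera (adjusted p = 0.171). ADAM10, the main alpha-secretase, had 3 counts in the RIP libraries against 261 ± 28.8 CPM in input, a ratio of 172 (95% counting interval 58.7 to 837; edgeR adjusted p = 0.000534). PSEN2, a membrane protease, was at least 7.16-fold lower (edgeR adjusted p = 0.0237), a call that ended in 4 of 12 alternatives and left-out libraries. APLP1, an APP relative, rose from 29.7 to 167 ± 116 CPM (2.49, SE 0.58, edgeR adjusted p = 0.0259), a call that ended in 5 of 13 alternatives and left-out libraries. PHGDH mRNA itself was not past the threshold (log2 fold change 0.89, SE 1.48, edgeR adjusted p = 0.699), with 1.10 and 207 CPM in the RIP replicates and 53.1 and 59.1 CPM in the inputs. Without RIP replicate 2, PHGDH was lower in RIP (log2 fold change -5.56, edgeR adjusted p = 0.0174). APP (0.00, SE 0.48, adjusted p = 0.998), BACE1 (2.5, SE 1.06, adjusted p = 0.131), CHUK (0.74, SE 1.64, adjusted p = 0.777) and HMGB1 (0.52, SE 0.33, adjusted p = 0.291) were not past it in edgeR. Without RIP replicate 1, CHUK was lower (log2 fold change -7.00, edgeR adjusted p = 0.0329).

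Glial and other genes went both ways without serum. Of 13 radial glia genes, 4 rose and 3 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.208), and of 12 astrocyte genes 2 rose and 2 fell (0.981). The neural transcription factors SOX2 (log2 fold change 4.83, SE 0.39, edgeR adjusted p = 0.000891) and SOX9 (2.84, SE 0.30, adjusted p = 0.00227) rose, as did VIM, an intermediate filament protein (3.28, SE 0.44, adjusted p = 0.00583). GFAP, the filament protein of astrocytes, fell from 238 to 21.7 CPM (log2 fold change -3.45, SE 0.44, edgeR adjusted p = 0.00478), and FABP7 fell by 0.80 (SE 0.15, adjusted p = 0.0161), a call that ended in 5 of 13 alternatives and left-out libraries. Of 15 genes of IKK, HMGB1 and autophagy, 3 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.797). GABARAP rose by 2.21 on the log2 scale (SE 0.22, edgeR adjusted p = 0.00200), and BECN1, with 1 RIP count, was lower at a ratio of 181 (95% counting interval 32.2 to 7157; adjusted p = 0.0141). VEGFA rose by 4.58 (SE 0.45, edgeR adjusted p = 0.00192), one of 17 hypoxia and glycolysis genes of which 1 rose and 1 fell (camera adjusted p = 0.946). Of 8 nuclear long non-coding RNAs, 3 rose and 1 fell (camera adjusted p = 0.203). MALAT1 rose by 1.32 (SE 0.09, edgeR adjusted p = 0.000392) but fell under cyclic loess scaling (log2 fold change -0.89), and NORAD rose by 1.54 (SE 0.18, adjusted p = 0.00390), a call that ended in 4 of 13. CLU rose by 1.28 (SE 0.33, edgeR adjusted p = 0.0333), a call that ended in 6 of 13 alternatives and left-out libraries. Of 11 Alzheimer risk and tau genes, 1 rose and 2 fell (camera adjusted p = 0.946).

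The remaining lists were not past camera without serum. Of 15 extracellular matrix genes, 1 rose and 6 fell (camera adjusted p = 0.203), and of 7 mesenchyme genes 0 rose and 3 fell (0.525). Both include COL1A1, which had 2 RIP counts and was lower at a ratio of 26.8 (95% counting interval 7.2 to 225; edgeR adjusted p = 0.0352), a call that ended in 6 of 13 alternatives and left-out libraries. Of 17 proliferation genes 1 rose and 3 fell (camera adjusted p = 0.723), of 21 translation factors 4 rose and 3 fell (0.525), and of 14 stress and unfolded protein response genes 3 rose and 1 fell (0.268). Of 7 immediate early genes 2 rose and 1 fell (camera adjusted p = 0.517) and of 7 inhibitory neuron genes 1 rose and 1 fell (0.171). Of 5 non-coding RNAs of ribonucleoproteins 1 rose (camera adjusted p = 0.111), and of 11 serine and one-carbon metabolism genes 1 fell (0.268). Of 10 interferon genes and 5 inflammation genes, 0 passed in edgeR in either direction, with camera adjusted p of 0.981 and 0.887. Lists too short for camera were oligodendrocyte lineage (3 measured), choroid plexus (3), surface epithelium (2), retina (1) and muscle and cartilage (1), with 0 members past the threshold in edgeR. With members at 0 counts set to their bound, the median of the proliferation list was -0.92 in place of -2.67, of extracellular matrix -0.65 in place of -1.86 and of mesenchyme -2.08 in place of -3.82. The test pointed up while the median was negative for Alzheimer genes (-0.17), translation factors (-0.03) and astrocytes (-0.44), and down with a median of 0.50 for inflammation.

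The count of genes without serum moved most when single libraries were left out. Without input replicate 1 the edgeR count fell to 208 genes and without input replicate 2 to 207, while without RIP replicate 1 it rose to 4172 and without RIP replicate 2 to 4087. With a replicate block it was 928 and with only the 4 libraries of this comparison 368. Of 44 genes described here as past the threshold, 23 were not past it without input replicate 1 and 23 without input replicate 2. The median log2 fold change of all genes was -0.26 with TMM, -0.72 with library size alone and -0.03 with cyclic loess. The scaling changed the split more than the total: library size scaling called 811 genes higher and 1948 lower, and cyclic loess 1409 and 1133. With the stricter filter of 50 counts, which tested 6911 genes, 1118 were higher and 972 lower. The calls of SYN1, SLC17A7, HMGCS1, MSMO1, MYPOP, SAP30, BECN1, H1-2 and UBAP1 each ended in 3 of 13 alternatives and left-out libraries.

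The second comparison asked the same of serum-treated organoids, on other libraries. Most ribosomal protein transcripts (35 of 44) were again higher in RIP than in input, and part of those of nuclear oxidative phosphorylation (9 of 32), histones (2 of 6) and general neuronal genes (5 of 16). Of these lists, only ribosomal proteins passed camera with the correlation estimated (each of the others had an adjusted p = 0.300 with an estimated correlation). RPL35 stood at 3950.3 ± 56.0 CPM in RIP against 133 ± 12.9 in input (log2 fold change 4.89, SE 0.15, edgeR adjusted p = 3.48e-05). PRR36 rose from 5.42 ± 0.900 to 2017 ± 447 CPM (8.52, SE 0.44, edgeR adjusted p = 0.000206) and DCLK2 from 5.96 ± 0.914 to 1457 ± 435 CPM (7.91, SE 0.72, adjusted p = 0.00164). In edgeR, 1011 genes were higher in RIP and 1246 lower, and 4028 had an unadjusted p under 0.05. For exact p-values 553 would be expected, and more by chance here, since 8.56% of unchanged genes in simulated data were under 0.05. Of the genes past the threshold, 465 of the lower had 0 counts in both RIP libraries and 10 of the higher had 0 in both inputs.

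CTDNEP1, a phosphatase of the nuclear envelope, rose from 6.2 ± 1.76 to 1058 ± 568 CPM with serum (log2 fold change 7.39, SE 0.56, edgeR adjusted p = 0.000725). MUC1, a membrane mucin with 1 input count, was higher at a ratio of 591 (95% counting interval 105 to 23424; edgeR adjusted p = 0.00389). RASSF10 was at least 20.8-fold higher (edgeR adjusted p = 0.0309) and HAPLN4, a link protein of the perineuronal matrix, at least 19.8-fold higher (adjusted p = 0.0176). The RASSF10 call ended in 4 of 12 alternatives and left-out libraries. NAPB, a vesicle fusion factor of neurons, was at least 85.1-fold lower (edgeR adjusted p = 0.00365), ELMO2 at least 83.4-fold (0.00314), CAP1 at least 71.2-fold (0.00408), and UBAP1 and CDC42SE2 at least 52.5-fold each (0.00677 and 0.00337). These bounds again cover counting error only. Of 5306 genes with at least 50 counts in one RIP replicate with serum, 242 had 0 in the other. NORAD, a long non-coding RNA that binds Pumilio proteins, rose from 186 ± 12.2 to 3251 ± 566 CPM (log2 fold change 4.13, SE 0.20, edgeR adjusted p = 0.000151). HSPA5, the main chaperone of the endoplasmic reticulum, fell from 962 ± 71.1 to 105 ± 45.3 CPM (log2 fold change -3.19, SE 0.36, edgeR adjusted p = 0.00337).

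Of 44 cytosolic ribosomal protein transcripts, 35 rose and 1 fell with serum (38 and 1 adjusted over the list alone), with a median log2 fold change of 2.15. The camera adjusted p was 9.60e-26, and the call held (adjusted p = 0.0148 with an estimated correlation). RPL19 rose by 4.0 on the log2 scale (SE 0.13, edgeR adjusted p = 3.57e-05) and RPS15 by 3.68 (SE 0.17, adjusted p = 0.000123). Without input replicate 1, 19 of the 44 rose in edgeR, and without input replicate 2, 18 did. The listed transcripts made up 8.38% ± 0.501 of RIP and 1.80% ± 0.0141 of input counts. Of 32 nuclear oxidative phosphorylation genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.0208; adjusted p = 0.300 with an estimated correlation). ATP5ME rose by 5.24 (SE 0.30, edgeR adjusted p = 0.000243), UQCRQ by 2.97 (SE 0.21, adjusted p = 0.000651) and NDUFB2 by 2.79 (SE 0.28, adjusted p = 0.00245). Of 13 mitochondrially encoded genes, 4 rose and 2 fell, not past camera (adjusted p = 0.0562). ND4 rose from 3299 ± 39.7 to 11091 ± 3398 CPM (log2 fold change 1.75, SE 0.19, edgeR adjusted p = 0.00300) and ND1 by 1.79 (SE 0.37, adjusted p = 0.0229), where the ND1 call ended in 4 of 13 alternatives and left-out libraries.

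Of 6 histone genes, 2 rose and 0 fell with serum (3 and 0 adjusted over the list alone; camera adjusted p = 0.0454; adjusted p = 0.300 with an estimated correlation). They were H1-2 (log2 fold change 5.14, SE 0.65, edgeR adjusted p = 0.00504) and H4C3 (2.34, SE 0.35, adjusted p = 0.00895). Of 16 general neuronal genes, 5 rose and 0 fell, also over the list alone (camera adjusted p = 0.0105; adjusted p = 0.300 with an estimated correlation). Of 12 excitatory neuron genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.0192; adjusted p = 0.300 with an estimated correlation). Under cyclic loess, 6 general neuronal genes rose and 2 fell. GAP43 rose by 2.93 (SE 0.17, edgeR adjusted p = 0.000243) and SYN1 by 7.05 (SE 0.81, adjusted p = 0.00355). NRGN rose by 4.79 (SE 0.65, edgeR adjusted p = 0.00646) and SLC17A7 by 3.36 (SE 0.44, adjusted p = 0.00583). SOX2 rose by 4.64 (SE 0.39, edgeR adjusted p = 0.00121) and SOX9 by 2.89 (SE 0.30, adjusted p = 0.00260). VIM rose by 3.08 (SE 0.43, edgeR adjusted p = 0.00764) and VEGFA by 4.94 (SE 0.46, adjusted p = 0.00167). FABP7 fell by 1.40 (SE 0.15, edgeR adjusted p = 0.00300) and GFAP by 1.79 (SE 0.40, adjusted p = 0.0274).

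Of 19 cholesterol synthesis genes, 0 rose and 4 fell with serum (0 and 5 adjusted over the list alone), not past camera (adjusted p = 0.0563). IDI1 fell by 2.42 on the log2 scale (SE 0.29, edgeR adjusted p = 0.00408), HMGCS1 by 2.31 (SE 0.36, adjusted p = 0.0104) and MSMO1 by 2.65 (SE 0.49, adjusted p = 0.0175). Of 17 amyloid precursor processing genes, 1 rose and 5 fell (camera adjusted p = 0.305). ADAM10 fell from 263 ± 7.37 to 21.2 ± 3.09 CPM (log2 fold change -3.63, SE 0.41, edgeR adjusted p = 0.00347). PSEN2 was at least 5.23-fold lower (edgeR adjusted p = 0.0284). APLP1 rose from 42.9 to 399 ± 38.2 CPM (3.21, SE 0.59, edgeR adjusted p = 0.0175). PHGDH mRNA stood at 406 and 161 CPM in RIP and 53.9 and 77.6 CPM in input (log2 fold change 2.11, SE 1.51, edgeR adjusted p = 0.356). APP (1.07, SE 0.48, adjusted p = 0.158), BACE1 (0.97, SE 1.02, 0.534), CHUK (0.11, SE 1.63, 0.969) and HMGB1 (0.45, SE 0.33, 0.364) were not past the threshold in edgeR.

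**Figure D2:**
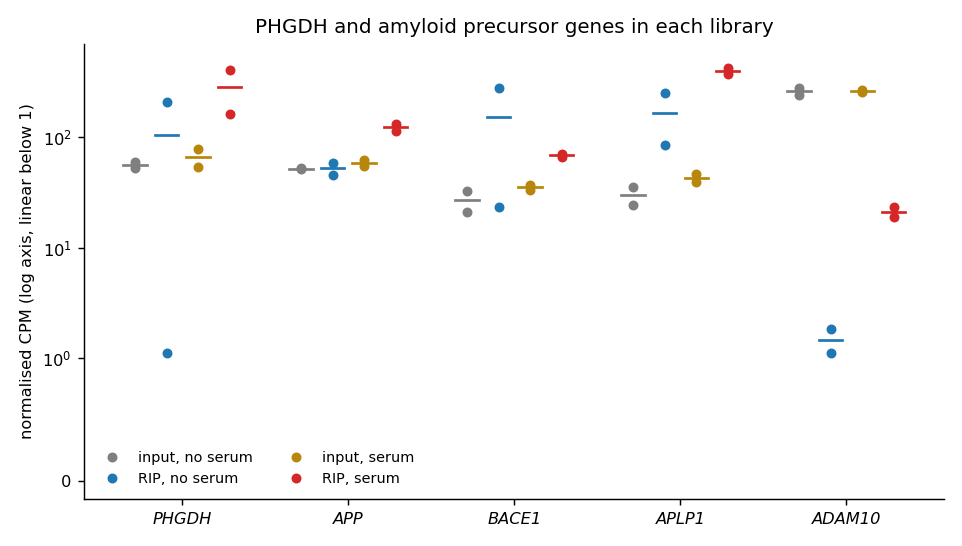
Normalised CPM of PHGDH, APP, BACE1, APLP1 and ADAM10 in each of the 8 libraries, on an axis that is linear near 0 and logarithmic above. ADAM10 lies lower in all 4 RIP libraries than in the inputs, and PHGDH ranges from 1.10 to 406 CPM in RIP.

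Autophagy and matrix genes with serum included GABARAP, which rose by 2.00 on the log2 scale (SE 0.22, edgeR adjusted p = 0.00308), and ULK1, which rose by 3.59 (SE 0.73, adjusted p = 0.0229). BECN1, with 1 RIP count, was lower at a ratio of 186 (95% counting interval 33.2 to 7377; edgeR adjusted p = 0.0160). COL1A1, with 3 RIP counts, was lower at a ratio of 93.2 (31.7 to 453; edgeR adjusted p = 0.0200), a call that ended in 3 of 13 alternatives and left-out libraries. Of 15 genes of IKK, HMGB1 and autophagy, 3 rose and 2 fell (camera adjusted p = 0.881), of 15 matrix genes 0 rose and 4 fell (0.102), and of 13 radial glia genes 5 rose and 1 fell (0.102). MALAT1 rose by 0.62 (SE 0.08, edgeR adjusted p = 0.00684) but fell under cyclic loess (log2 fold change -0.99). CLU was at 1.04 (SE 0.33, edgeR adjusted p = 0.0645), not past the threshold.

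With serum, the edgeR count fell to 143 genes without input replicate 1 and to 129 without input replicate 2, and 27 of the 44 genes described as past the threshold were not past it in each of these cases. The median log2 fold change of all genes was -0.25 with TMM, -0.53 with library size alone and -0.07 with cyclic loess. The share of called genes that were higher was 44.8% with TMM and 56.5% with a minimum of 50 counts. The calls of HAPLN4 and PSEN2 each ended in 3 of 12 alternatives and left-out libraries, and those of GFAP, ULK1 and MSMO1 in 3 of 13.

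The comparisons without and with serum share no library, but they come from one model with one spread per gene. Genes with a small spread therefore tend to pass in both, so calls were not independent. The expected numbers given here are a reference only. Of genes past the edgeR threshold in each, 744 were higher in both, where 101 would be expected if calls were independent, and 740 were lower in both, where 172 would be expected. Opposite calls were 3 and 4 genes. Across genes, log2 fold changes had a correlation of 0.60 (Spearman 0.64), and 75.1% had the same sign. RPL35, RPL19, ATP5ME, DCLK2, PRR36, GAP43 and SOX2 were past the threshold and higher in both conditions under every alternative and with each library left out, and ELMO2 was lower.

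**Figure D3:**
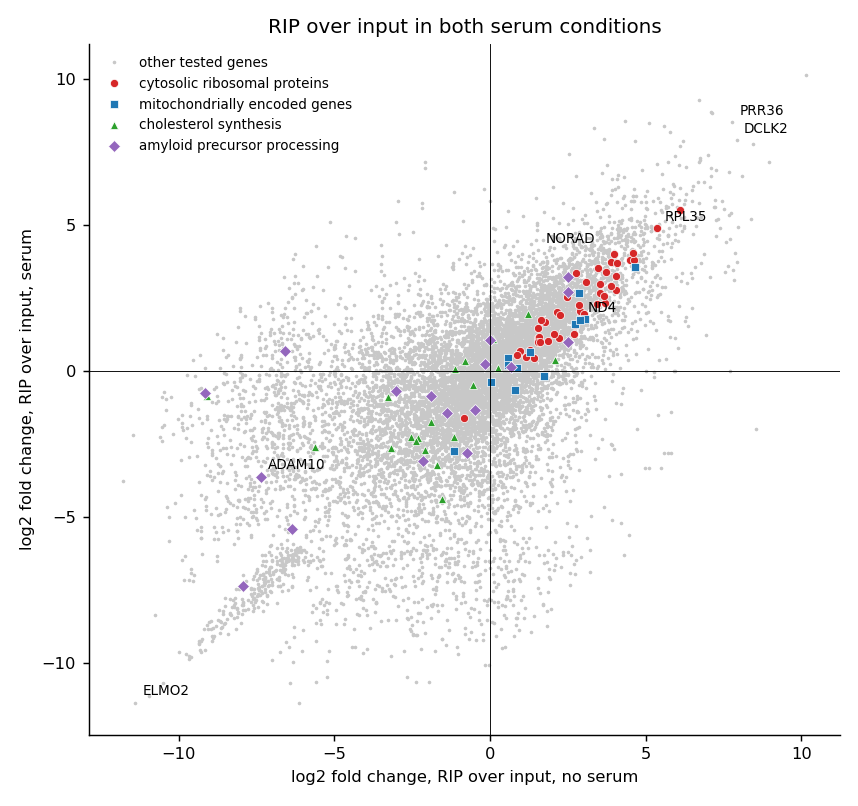
Log2 fold change of RIP over input without serum (horizontal) against with serum (vertical), one point per tested gene, with members of several lists coloured and 7 genes labelled. RPL35, DCLK2 and PRR36 lie high on both axes, ELMO2 and ADAM10 low on both, and NORAD is higher on the vertical axis.

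**Figure D4:**
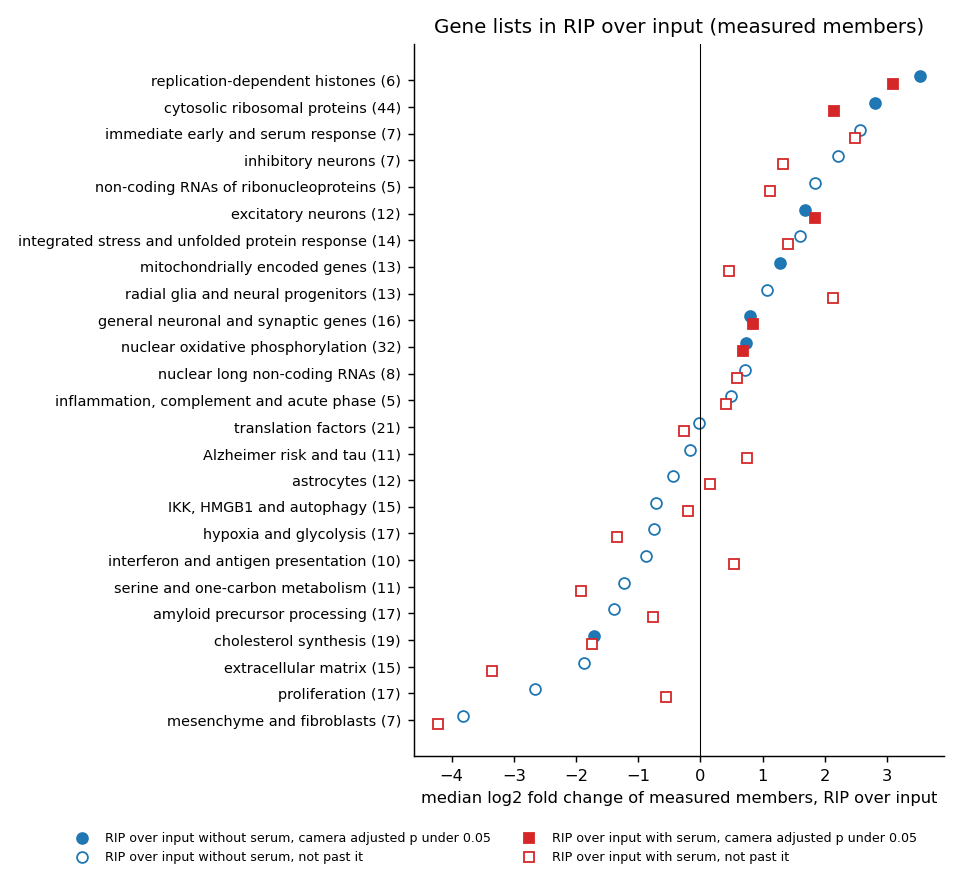
Median log2 fold change of RIP over input for each list of at least 5 measured genes (number in brackets), without serum as circles and with serum as squares. Filled symbols have a camera adjusted p under 0.05 with the preset correlation, and those of histones and ribosomal proteins lie farthest to the right.

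The third comparison tested whether the enrichment over input differed with serum. With serum, mitochondrially encoded and ribosomal protein transcripts as lists were less enriched in RIP by camera, calls that were lost when the correlation was estimated (adjusted p = 0.515 and 0.250 with an estimated correlation), and no single gene passed. CYTB stood at 3501 ± 74.2 CPM in RIP without serum and 1286 ± 232 with serum, against 2011 and 2008 CPM in the inputs (interaction log2 fold change -1.44, SE 0.22, edgeR adjusted p = 0.167). NORAD went the other way, at 541 ± 9.43 CPM in RIP without serum and 3251 ± 566 with serum, with inputs at 186 and 186 CPM (2.59, SE 0.26, edgeR adjusted p = 0.167). In edgeR, 0 genes passed and 1451 had an unadjusted p under 0.05, where 553 would be expected for exact p-values. More are expected by chance here, since 9.32% of unchanged genes in simulated data were under 0.05. The count of 0 says little, because on simulated data this test recovered 0% of 8-fold changes and 20% of the largest changes simulated. DESeq2 called 403 genes, limma-voom with cyclic loess 42, edgeR with no filter 40 and limma-voom with separate variances 4.

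The other genes with the smallest p in this interaction, each with an edgeR adjusted p of 0.167, were SAR1B, CORO1C, IGFBPL1 and DMAC2. SAR1B and CORO1C had 0 counts in RIP without serum and 58.8 ± 0.489 and 23.0 ± 4.11 CPM with serum. IGFBPL1, an insulin-like growth factor binding protein relative, was at 102 ± 22.0 CPM in RIP without serum and 2.42 ± 1.06 with serum, and DMAC2, an assembly factor of complex I, at 1.56 ± 0.915 and 177 ± 6.39 CPM. ADAM10 (log2 fold change 3.74, SE 0.62, edgeR adjusted p = 0.179) and HSPA5 (-2.37, SE 0.47, adjusted p = 0.200) did not pass. Neither did PHGDH (1.22, SE 2.07, edgeR adjusted p = 0.878), APP (1.07, SE 0.68, 0.536), BACE1 (-1.53, SE 1.43, 0.706), CHUK (-0.62, SE 2.31, 0.971) or HMGB1 (-0.07, SE 0.46, adjusted p = 1).

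For ribosomal proteins the median interaction was -0.60 on the log2 scale (camera adjusted p = 3.19e-06; adjusted p = 0.250 with an estimated correlation). RPL15 (-0.79, edgeR adjusted p = 0.235), RPS6 (-1.11, 0.240) and RPL13 (-1.28, 0.255) were among its members with the smallest p. For mitochondrially encoded genes the median was -1.12 (camera adjusted p = 9.56e-05; adjusted p = 0.515 with an estimated correlation), with 0 higher and 3 lower adjusted over the list alone. Its members included ND4 (-1.15, edgeR adjusted p = 0.215) and ND2 (-1.90, 0.216). For nuclear oxidative phosphorylation the median was -0.59 (camera adjusted p = 0.0462; adjusted p = 0.515 with an estimated correlation), and the call ended with library size scaling (camera adjusted p = 0.166). The mitochondrial genome took 3.07% ± 0.525 of RIP counts with serum and 5.19% ± 0.162 without. In edgeR, 840 genes passed without RIP replicate 1 of the no-serum group, 520 without its replicate 2 and 249 without RIP replicate 2 of the serum group.

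The fourth comparison asked how serum changed total RNA. Inputs with serum had more RNA of MT2A and MT1X, of 3 collagens and of part of the listed genes of hypoxia and glycolysis (10 of 17), proliferation (8 of 17) and astrocytes (7 of 12), and slightly less of 4 of 19 cholesterol synthesis genes. As lists, these passed camera but not with the correlation estimated (adjusted p = 0.156 with an estimated correlation for glycolysis, proliferation and astrocytes, and 0.314 for cholesterol synthesis). MT2A, a metal-binding metallothionein, stood at 33.7 ± 4.39 CPM with serum and 2.01 ± 0.530 without (log2 fold change 3.97, SE 0.40, edgeR adjusted p = 3.55e-11). These values, and those of the next paragraphs, come from edgeR on the 4 input libraries alone. There edgeR draws each gene's spread towards that of all genes, so a small p-value does not show that its replicates were close. In the 8-library edgeR model, whose spread includes that of the RIP libraries, 0 genes passed and 21 had an unadjusted p under 0.05. DESeq2 called 1 gene, limma-voom with cyclic loess 0 and limma-voom with separate variances 256. On the 4 input libraries alone, edgeR called 566 of 11056 genes, 322 higher and 244 lower, with 2000 at an unadjusted p under 0.05, 61 at least 2-fold higher and 33 at least 2-fold lower. The smallest p-values of the 8-library model were for ZFP36L1 (log2 fold change 0.66, SE 0.14), MT2A, CRYAB, a small heat shock protein (1.53, SE 0.38), ACSBG1 and MT1G, each with an edgeR adjusted p of 1.

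In the input libraries alone, MT1X rose from 5.53 ± 0.248 to 47.6 ± 1.27 CPM (log2 fold change 3.10, SE 0.29, edgeR adjusted p = 2.69e-12). ACSBG1, an acyl-CoA synthetase, rose by 3.58 (SE 0.47, edgeR adjusted p = 1.16e-07) and ANXA1, an annexin, by 2.61 (SE 0.23, adjusted p = 1.14e-12). Further increases were A2M, a protease inhibitor (2.58, SE 0.59, edgeR adjusted p = 0.00306) and MANF, a factor secreted under endoplasmic reticulum stress (1.89, SE 0.56, adjusted p = 0.0335), whose call ended in 3 of 6 alternatives and left-out libraries. SEMA5A, a guidance protein, rose by 1.82 (SE 0.23, edgeR adjusted p = 6.01e-08). KRT5, a keratin of surface epithelium, fell from 10.8 ± 1.5 to 1.52 ± 0.390 CPM (-2.78, SE 0.59, edgeR adjusted p = 0.00122). SCN9A, a sodium channel, fell by 2.14 (SE 0.50, edgeR adjusted p = 0.00390) and NEFH, the heavy neurofilament, by 1.7 (SE 0.48, adjusted p = 0.0214), whose call also ended in 3 of 6. Others that fell were ZNF782 (log2 fold change -2.18, SE 0.62), LACC1 (-2.08, SE 0.58), MAB21L1 (-2.01, SE 0.52) and VEPH1 (-1.59, SE 0.38), with edgeR adjusted p from 0.00575 to 0.0244. TTR, the main secreted protein of choroid plexus, passed as lower in edgeR (adjusted p = 1.68e-08), but 989 of its input counts lay in replicate 2 without serum, 2 in replicate 1 and 0 in both inputs with serum.

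Among the lists in the input libraries alone, 10 of 17 hypoxia and glycolysis genes rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 1.02e-15). Of 17 proliferation genes 8 rose (12 adjusted over the list alone; camera adjusted p = 3.87e-14), and of 12 astrocyte genes 7 rose (7 adjusted over the list alone; 4.51e-11). These 3 calls were lost with the correlation estimated (adjusted p = 0.156 with an estimated correlation for each). GAPDH, the glycolytic dehydrogenase, rose from 1558 ± 65.2 to 2400.5 ± 46.0 CPM (log2 fold change 0.63, SE 0.05, edgeR adjusted p = 1.66e-15). ADM, a hypoxia-induced peptide, rose by 1.19 (SE 0.18, edgeR adjusted p = 2.90e-06), PGAM1 by 0.56 (SE 0.10, adjusted p = 0.000129) and ENO1 by 0.37 (SE 0.06, adjusted p = 3.88e-05). The spindle and cell cycle genes NUSAP1 (0.89, SE 0.12, edgeR adjusted p = 4.49e-07), TPX2 (0.87, SE 0.14, adjusted p = 2.16e-05), CDK1 (0.70, SE 0.13, adjusted p = 0.000332) and TOP2A (0.57, SE 0.11, adjusted p = 0.000457) rose. GFAP rose from 273 ± 24.3 to 483 ± 10.8 CPM (0.83, SE 0.08, edgeR adjusted p = 4.15e-12). CD44, a hyaluronan receptor, rose by 1.52 (SE 0.27, edgeR adjusted p = 9.67e-05), AGT, angiotensinogen, by 1.12 (SE 0.20, adjusted p = 9.72e-05) and SPARCL1 by 1.04 (SE 0.21, adjusted p = 0.000506).

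Of 15 extracellular matrix genes in the inputs alone, 6 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 4.23e-09; adjusted p = 0.186 with an estimated correlation). Of 7 mesenchyme genes 3 rose and 0 fell (camera adjusted p = 1.31e-08; adjusted p = 0.186 with an estimated correlation), the 3 collagens that both lists hold. COL1A1 rose from 32.6 ± 18.4 to 147 ± 37.4 CPM (log2 fold change 2.26, SE 0.18, edgeR adjusted p = 1.07e-14). COL3A1 rose by 2.01 (SE 0.24, edgeR adjusted p = 1.05e-08), COL1A2 by 1.79 (SE 0.23, adjusted p = 3.79e-08) and TNC, tenascin C, by 0.78 (SE 0.07, adjusted p = 4.15e-12). PDGFRB, a pericyte and fibroblast receptor, was at -0.38 (SE 0.24, edgeR adjusted p = 0.413). Of 13 radial glia genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.00523; adjusted p = 0.351 with an estimated correlation). HOPX, a marker of outer radial glia, rose from 116 ± 12.3 to 254 ± 15.4 CPM (1.12, SE 0.11, edgeR adjusted p = 5.29e-12). VIM rose by 0.74 (SE 0.13, edgeR adjusted p = 9.72e-05), while PTPRZ1 fell by 0.30 (SE 0.06, adjusted p = 0.000162). Of 19 cholesterol synthesis genes 0 rose and 4 fell (0 and 8 adjusted over the list alone; camera adjusted p = 6.82e-05; adjusted p = 0.314 with an estimated correlation). Among them were HMGCS1 (log2 fold change -0.37, SE 0.06, edgeR adjusted p = 1.38e-05), MSMO1 (-0.36, SE 0.06, adjusted p = 1.14e-05) and IDI1 (-0.30, SE 0.07, adjusted p = 0.00318). Without serum replicate 1, only 1 of these fell past the threshold.

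Of 14 stress and unfolded protein response genes in the inputs alone 3 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.000211; adjusted p = 0.186 with an estimated correlation). They were HSPA5 (log2 fold change 0.40, SE 0.06, edgeR adjusted p = 8.03e-07), DDIT3 (0.52, SE 0.14, adjusted p = 0.0111) and PDIA4 (0.43, SE 0.12, adjusted p = 0.0147), and the calls of DDIT3 and PDIA4 ended in 3 of 8 alternatives and left-out libraries. Of 15 genes of IKK, HMGB1 and autophagy 3 rose (4 adjusted over the list alone; camera adjusted p = 0.00904; adjusted p = 0.351 with an estimated correlation). They were the lysosomal protein LAMP2 (log2 fold change 0.45, SE 0.08, edgeR adjusted p = 0.000265), MAP1LC3B (0.87, SE 0.20, adjusted p = 0.00316) and HMGB2 (0.46, SE 0.11, adjusted p = 0.00715). Of 44 ribosomal protein genes 1 rose (RPS19) and 5 adjusted over the list alone (camera adjusted p = 1.30e-06; adjusted p = 0.161 with an estimated correlation). Of 32 nuclear oxidative phosphorylation genes 3 rose (camera adjusted p = 5.55e-06; adjusted p = 0.189 with an estimated correlation). Of 21 translation factors 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.00231; adjusted p = 0.189 with an estimated correlation). Of 13 mitochondrially encoded genes 0 rose and 2 fell (0 and 7 adjusted over the list alone; camera adjusted p = 0.00231; adjusted p = 0.189 with an estimated correlation). They were COX1 (log2 fold change -0.28, SE 0.05, edgeR adjusted p = 2.74e-05) and ND5 (-0.24, SE 0.05, adjusted p = 0.00217). ND5 is uncertain because it adjoins ND6 on the other strand and the libraries did not keep the strand. The histone list passed with 0 of 6 members called over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0462; adjusted p = 0.314 with an estimated correlation).

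Lists not past camera in the inputs alone included amyloid precursor processing (0 of 17 genes called; adjusted p = 0.735), serine and one-carbon metabolism (0 of 11; 0.999) and Alzheimer risk (CLU alone of 11 rose, by 0.33, SE 0.05; 0.168). Excitatory neurons (0 of 12; camera adjusted p = 0.222) and inhibitory neurons (1 of 7; 0.938) were not past it either. General neuronal genes went both ways (2 rose and 2 fell of 16; camera adjusted p = 0.659), with NEFL (log2 fold change 0.58, edgeR adjusted p = 6.12e-05) among the higher and SNAP25 (-0.30, 0.00380) and MAP2 (-0.23, 0.00858) lower, where the MAP2 call ended in 4 of 8 alternatives and left-out libraries. Nuclear long non-coding RNAs (1 rose and 2 fell of 8; camera adjusted p = 0.164) included NEAT1 (0.72, edgeR adjusted p = 1.04e-12), MIAT (-0.51, 1.74e-09) and MALAT1 (-0.32, 2.07e-09). Interferon genes (2 rose and 1 fell of 10; camera adjusted p = 0.164) included B2M, which rose by 0.90 (SE 0.14, edgeR adjusted p = 3.75e-06). Inflammation (0 of 5; camera adjusted p = 0.200), immediate early genes (0 of 7; 0.492) and non-coding RNAs of ribonucleoproteins (0 of 5; 0.0638) had 0 genes past edgeR. PHGDH (0.23, SE 0.15, edgeR adjusted p = 0.447), APP (0.16, SE 0.15, 0.641), BACE1 (0.33, SE 0.20, 0.404), CHUK (0.27, SE 0.32, 0.720) and HMGB1 (0.01, SE 0.06, 0.942) were not past the threshold.

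In the 8-library model, camera put 15 lists past the threshold for serum in input, 13 up and 2 down (mitochondrially encoded genes, adjusted p = 0.0390, and cholesterol synthesis, 0.0287), with 0 members past edgeR. Of these, 0 passed with an estimated correlation (smallest adjusted p = 0.0516 with an estimated correlation, for proliferation). In the inputs alone, 299 genes passed in edgeR without serum replicate 1 and 272 without serum replicate 2, and DESeq2 called 74.

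**Figure D5:**
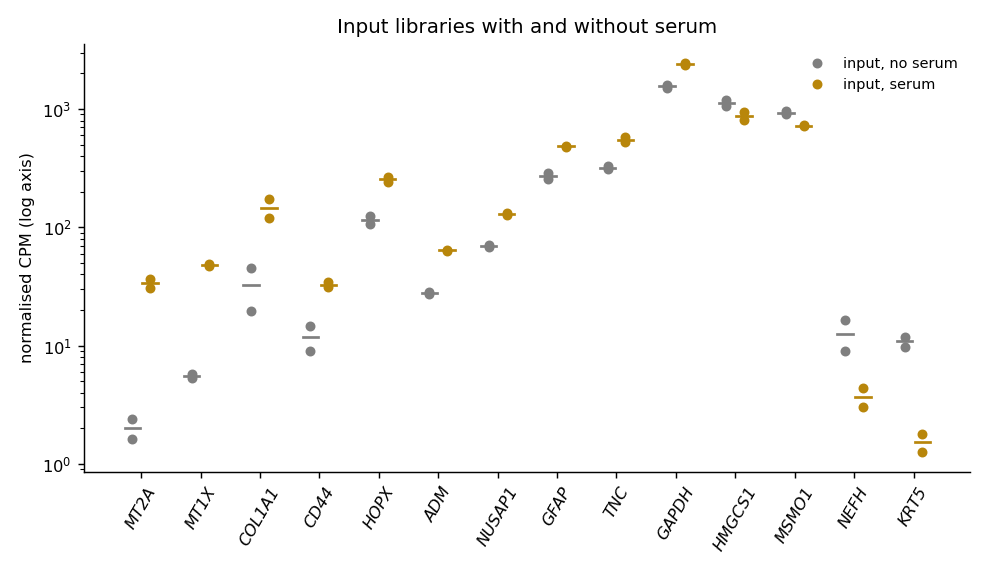
Normalised CPM, on a logarithmic axis, of 14 genes in the 4 input libraries, coloured by serum. Each point is 1 library, and MT2A, MT1X and COL1A1 are the genes with the widest separation upwards and KRT5 downwards.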

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

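Of the tests in this part, the thinning of input libraries to RIP depth, the simulation of libraries limited by molecule number and the test of TTR reads crossing between libraries were chosen only after the result had been seen.

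The enrichment over input of 3 gene lists differed between organoids without and with serum in the interaction test by camera. These were ribosomal proteins (adjusted p = 3.19e-06), mitochondrially encoded genes (9.56e-05) and nuclear oxidative phosphorylation (0.0462), all less enriched with serum, and 0 of the 3 passed with an estimated correlation. Table lines without a gene name, outside the genes compared, took 0.418% of the counts of RIP replicate 1 and 0.283% of RIP replicate 2 with serum, above the highest input library (0.241%). Groups of 2 libraries are too small for a test of single outlying libraries.

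Replicate RIP libraries differed far more than replicate inputs (SD of log2 differences 2.24 and 1.97 with each pair scaled by library size alone). Lower depth was argued against: input pairs thinned to 1011360 counts reached an SD of at most 0.437 over 20 draws. A limit set by few molecules of each RNA before amplification predicts that spread falls steeply as input abundance rises, but the slope of log dispersion on log input CPM was only -0.228 (95% bootstrap interval -0.242 to -0.215), and libraries simulated from 175686 molecules gave a slope of -1.25, an SD of at most 1.2 and at most 14 genes at 0 in one replicate and 50 or more in the other. This argues against a limit proportional to abundance in the input as the sole source of spread. The simulation held no other source of spread, so such a limit may still add to others. Nor does the slope cover a limit that acts on whatever fraction of each RNA the immunoprecipitation kept. Loss during immunoprecipitation stays open. Differences in total RNA between organoid batches were argued against for the inputs, whose replicates had an SD of 0.383 and 0.335 (without and with serum). Inputs also correlated at 0.970 to 0.977 across serum conditions. Batch differences stay open if RIP libraries came from other organoids, or if batches differed in the immunoprecipitation itself. No biological explanation was tested.

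Transcripts of ribosomal proteins were higher in RIP than in input, with median log2 fold changes of 2.81 without and 2.15 with serum. Short, abundant transcripts in general were not the whole cause: among 10000 random lists matched on length and input abundance, the highest median was 1.36 without serum and 0.82 with serum. Reads moved between the genes and their pseudogenes were argued against, since the summed share of the genes and their annotated pseudogenes was at least 4.42-fold higher in the lowest RIP library than in the highest input (5.36-fold in the other condition). Recovery that does not depend on PHGDH, such as ribosomes held by the beads or the antibody, cannot be told apart from binding to PHGDH, because there were 0 control antibody libraries. GC content was not tested, and association with PHGDH remains a hypothesis.

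TTR had 989 counts in input replicate 2 without serum and 804 in RIP replicate 2 without serum, but 2 and 0 in replicate 1 and 0 in all libraries with serum. Reads crossing between libraries were argued against, as the lower of these libraries held 73.4% of the TTR CPM of the higher. Choroid plexus tissue in the organoids of that input is a candidate explanation: 9 other markers, summed, were 3.55-fold higher there than in the highest other input (95% interval 1.77 to 7.59, 31 against 12 counts, with 12 for FOLR1 and 9 for KCNJ13), although they had 0 counts in RIP replicate 2, and their sum was at least as high in the RIP libraries with serum (26.3 and 59.6 CPM of the library total, 27 and 78 counts), where TTR was at 0. AQP1 and SLC4A5 were left out of that sum because their counts had been seen (23 and 36 in that input, and 0 and 34 in RIP replicate 2). Whether same-numbered input and RIP libraries share organoids cannot be told apart from chance, since the share of input differences kept in sign was 48.6% of 35 genes without serum (95% exact interval 31.4 to 66.0) and 3 of 3 genes with serum (exact p = 0.25).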

How the results depend on the processing

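In this part, limma-voom with separate input and RIP variances and all alternatives of the test on input libraries alone were chosen after the data had been seen. For RIP against input, DESeq2, RLE size factors, library size, cyclic loess, separate variances and both filters kept the count of genes within 1.5-fold of the main count, and DESeq2 kept 2417 of the 2633 calls without serum and 2079 with serum. Without serum, a replicate block gave 928 genes and only the 4 libraries of the comparison 368, and leaving out single libraries gave 207 to 4172. With serum, the block gave 815 genes and leaving out single libraries 129 to 3064. Over all genes, deviations of same-numbered libraries had correlations of -0.0344 to 0.0262. Input replicates differed little beyond counting error (chi-square per degree of freedom 1.46 without and 1.10 with serum), so these correlations cannot decide whether organoids were shared. The numbers were not read as pairs, although shared organoids are not excluded. The interaction, at 0 genes in edgeR, had 403 with DESeq2, 42 with cyclic loess, 40 with no filter, 4 with separate variances and 0 to 840 with libraries left out. In the simulated interaction 78.7% of DESeq2 calls were false, as were 2 of 16 calls (12.5%) of the 8-library edgeR model. Serum in input, at 0 genes, had 1 with DESeq2, 566 with the 4 input libraries alone, 256 with separate variances and 0 with each input left out. On inputs alone, DESeq2 called 74 genes and leaving out a library left 272 to 513, while library size gave 612, a minimum of 50 counts 467 and a block 658. A library left alone in its group was assumed to vary like the other groups. With an estimated correlation, the lists past camera went from 7 to 1 without serum, from 5 to 1 with serum, from 3 to 0 for the interaction, from 15 to 0 for serum in input and from 14 to 0 on inputs alone. With a replicate block, camera no longer called histones and cholesterol synthesis without serum (adjusted p = 0.0514 each), and with serum it called mitochondrially encoded and immediate early genes as well (0.0484 each). In simulated RIP libraries, a list raised by design also missed the threshold with the estimated correlation (adjusted p = 0.0678 without and 0.121 with serum), so its loss there does not show that a list is unchanged. In simulated inputs the raised list passed camera (adjusted p = 0.000222 with an estimated correlation). That list was raised 4-fold in the 8-library model. On inputs alone, the median log2 fold change was 0.37 for hypoxia and glycolysis and 0.70 for proliferation. The simulation therefore cannot tell whether power was low for the input lists. Among the genes named, 4 cases reversed: PHGDH without RIP replicate 2 of the no-serum group (log2 fold change -5.56; -5.56 to 1.88 with single libraries left out), CHUK without RIP replicate 1 of that group (-7.00; -7.00 to 1.74), and MALAT1 with cyclic loess without serum (-0.89) and with serum (-0.99). Over all genes, cyclic loess reversed and called 4 of the main calls without serum and 1 with serum. Of 44 named genes past the threshold without serum, 19 kept their call under every alternative and left-out library, as did 16 of 44 with serum and 31 of 55 on inputs alone, counting the alternatives that gave a value. Calls that ended were most often those without an input library. The cause was not tested further, but the 8-library model takes one spread per gene from inputs and RIP libraries together. Its common coefficient of variation was 0.693, against 0.0443 in inputs and 1.07 in RIP libraries. It thus overstates the spread for serum in input and understates that of RIP libraries in RIP against input. Depth limited genes with few counts: a count of 0 in a RIP library allows up to 2.5 to 3.31 normalised CPM from counting error alone.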

Other observations

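None of the tests in this part was chosen after its result had been seen.

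RNA classes shifted between input and RIP. Long non-coding RNAs took 3.56% ± 0.185 of input counts and 5.46% ± 0.177 of RIP counts without serum, and 3.02% ± 0.0223 and 4.03% ± 0.0606 with serum (mean ± SD, n = 2). Protein-coding genes took 93.6% ± 0.185 and 88.4% ± 0.0496 without serum, and 94.4% ± 0.0363 and 92.1% ± 0.360 with serum. Genes higher in RIP in both conditions had a median length of 4116 bases and genes lower in both 4471. The median was 4673 for all tested genes and 1150 for the ribosomal protein list.

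Genes with more RNA in serum-treated inputs were also seen in RIP libraries. ZFP36L1, which binds AU-rich elements of mRNA, stood at 2099 ± 175 CPM in RIP without serum and 3333 ± 90.2 with serum, beside 244 ± 1.84 and 385 ± 11.6 CPM in the inputs. MT2A stood at 31.7 ± 25.4 and 134 ± 63.7 CPM in RIP, and MT1G was at 0 in RIP without serum and 36.6 ± 14.0 CPM with serum. ACSBG1, which rose with serum in the inputs, had 0 counts in all RIP libraries.

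A hypothesis was that serum-related differences in input RNA are carried into the RIP libraries. Of 532 genes that differed with serum in the inputs alone, 61.8% had the same sign of serum difference in RIP, against 51.7 and 53.2% for the other pairings of the 4 RIP libraries (Spearman correlation across genes 0.27). Such carry-over may therefore hold for part of these genes. Genes are not independent replicates, and 3 splits are too few to exclude chance.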
